A study of Mus musculus with 6 samples.

How the data were processed

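Liver DNA of mouse offspring at 32 weeks was hybridised to 6 two-colour Agilent arrays, 3 from chromium-restricted dams and 3 from control-diet dams. Per the labels, immunoprecipitated methylated DNA carried Cy5 (red) and input DNA carried Cy3 (green) on every array, with no dye swap. The tissue and title labels give liver, while the extraction label names fat. The labels say nothing of litters, so p-values measure only the spread between these samples.

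Per the file headers, the scans were read with Agilent Feature Extraction 11.0.1.1. The deposited processed signals are intensity values from which a local background had been subtracted and which had been dye-normalized by a linear factor per channel, with no lowess term, per the file headers. The linear factors were between 5.00 and 11.6 for the input channel and between 3.79 and 5.50 for the immunoprecipitated channel. The deposited scanner output also holds a log10 ratio of red over green per spot and a p-value of that ratio from the scanner software's error model, and these were not used in any test. The authors' series values are normalized log ratios whose method is not given in the sources used here. Its direction, red over green, was found by setting each column against that array's scanner values, and a log2 scale was assumed for the authors' table, since its log base is not stated. Its slope over probes was 0.946 to 1.04 on log2 ratios after normexp and 0.526 to 0.586 on log2 ratios of the processed signals, so its differences are smaller than those of the main values. The medians of its columns were 0.040, 0.037 and 0.035 for chromium-restricted arrays 1, 2 and 3, and 0.037, 0.037 and 0.031 for control arrays 1, 2 and 3. Its centring and any smoothing are not stated. Over probes, ratios of the uncorrected spot signals correlated with it at 0.908 to 0.914 on the 6 arrays, at 0.934 to 0.940 after averaging over probes within 250 bp to each side, and at 0.794 to 0.808 after averaging within 500 bp. It served as an alternative.

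Probe positions came from the array design, on mm9. The gene table given was of a later mouse build, and coordinates were not converted between builds. For this reason the gene-level fit, the gene lists and their set tests, the probe classes and the check on imprinted, germline and housekeeping genes, all planned, were not analysed here. The correction for GC content needs probe sequences or a genome of the same build and was not run.

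For each array the log2 ratio of the processed red over green signal was taken and centred on the median over probes that are not controls. No loess or quantile step was applied, since most probes of an immunoprecipitation array can carry signal. Centring removes any gain or loss shared by all probes. The 5827 control spots per array were left out. No other probe had repeated spots, so no averaging was needed. A probe with a flag for uneven pixels or population outliers in either channel on any array was left out (360 of 174638). Saturated spots were kept. A region was a run of probes on one chromosome with starts at most 1000 bp apart and at least 3 probes, and its value was the mean over its probes. The median spacing of probes within regions was 209 bp, and probes were 45 to 60 bases long.

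Differences are chromium-restricted minus control throughout. Probes and regions were fitted with limma 3.58.1 (lmFit and eBayes, group as the only term) in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05. Unadjusted p-values printed for single regions are limma's moderated ones. Tables were read with the R package data.table (version 1.17.8), and figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Values with 1 number per array were compared with two-sided exact permutation tests. Precision was limited by the number of arrays. The groups, the tests of the comparisons, the alternatives listed below and the rule for named regions were fixed before the data were examined. Alternatives and tests added later are named as such where their values are given. That rule took up to 12 regions per direction past the adjusted threshold, and, since none passed, those with the smallest unadjusted p among regions with full separation of the groups and a difference of at least 0.3 on the log2 scale. The rule asked for regions with a gene symbol; without symbols it was applied to all regions, and its parts on fixed genes could not be applied.

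The arrays with the same replicate number in both groups shared a scan, so the replicate block is also a scan block. All chromium-restricted arrays lay at slide position 2 and all control arrays at slide position 4, so slide position and group cannot be told apart.

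The region test was tested on simulated data over 21987 regions with 200 of them shifted. With independent noise of the measured size, 11.5% of shifts of 0.5 were recovered, 86.5% of shifts of 1 and 99.5% of shifts of 2 on the log2 scale, and unshifted regions made up 0%, 3.35% and 3.86% of the calls. With shifts added to the measured arrays, recovery was 0%, 93.5% and 100%. With no shift, 0 regions were called and 5.31% had an unadjusted p under 0.05.

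Alternatives were normexp background correction with an offset of 50, loess within arrays, quantile normalization, scaling to a common median absolute deviation, only probes well above background, flagged spots kept, the authors' table, the replicate block, a trended robust variance, array weights, an unmoderated statistic, other region definitions and leaving out each array in turn. The normexp correction used median spot signals and was fitted on all spots. Quantile normalization and scaling make the spread of arrays alike and were not applied to the interquartile range.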

Results

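DNA methylation was measured in the liver of mouse offspring at 32 weeks of age. The mothers (dams) had been given either a diet restricted in chromium, a trace element, or a control diet, and each group had 3 arrays. The assay was methylated DNA immunoprecipitation read on a microarray (MeDIP-chip), in which an antibody pulls down DNA fragments that carry methylated cytosine. Immunoprecipitated DNA was labelled with the red dye and input DNA with the green dye on the same array. A higher log2 ratio of red over green is therefore taken as more methylated DNA at a probe. The planned check of this on imprinted, germline and housekeeping genes was not run. After 360 probes with a spot flag were left out, 174278 probes on 21 chromosomes remained, and 21987 regions of at least 3 neighbouring probes were formed from them. A region held a median of 8 probes over 1645 bp. Positions are those of the array design on mouse genome build mm9, counted from 1. Genes at these positions were not analysed here.

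The arrays differed in the brightness of the input channel. The median background-subtracted input signal was 53.1, 83.9 and 46.1 scanner units on chromium-restricted arrays 1, 2 and 3, and 98.4, 38.1 and 60.5 on control arrays 1, 2 and 3. The group means were 61.0 ± 20.1 and 65.7 ± 30.4 (SD, n = 3 each; two-sided exact permutation p = 0.9). The immunoprecipitated channel had a median of 127 ± 15.0 in the chromium-restricted group and 124 ± 22.2 in the control group (SD, n = 3 each; exact permutation p = 0.9). Before probes with a spot flag were left out, 117793 of 174638 probes (67.4%) were well above background in both channels on all 6 arrays.

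The first comparison asked whether liver DNA methylation differed between offspring of chromium-restricted and control dams. With limma and Benjamini-Hochberg adjustment at 0.05, 0 of 21987 regions and 0 of 174278 probes differed between the groups. The lowest adjusted p was 1.0 at both levels. At an unadjusted p under 0.05 there were 197 regions (0.896%), 90 with higher and 107 with lower values in the chromium-restricted group, where 1099 would be reached by chance with independent errors. The corresponding count for probes was 2259 (1.30%), of which 1193 were higher and 1066 lower. The differences were small: the central 98% of regions lay between -0.21 and 0.19 on the log2 scale. The region with the highest difference reached 0.49 and the lowest -0.50. The 95% confidence interval of a region's difference extended by a median of 0.22 to each side, and that of a probe by 0.49. With shifts of known size added to the measured arrays, 0 of 200 regions shifted by 0.5 and 187 of 200 shifted by 1 were called. In simulated independent noise, 23 of 200 regions shifted by 0.5 were called, so most differences of that size in single regions would be missed with these arrays.

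Both groups were present in each of the 3 scans, 1 array of each group per scan. With the scan as a block, 0 regions and 0 probes passed the adjusted threshold and 112 regions and 2294 probes had an unadjusted p under 0.05. A single scan held 1 array per group and allowed no test, and the groups lay at different slide positions. Array weights estimated from the data gave 1654 regions and 53189 probes past the adjusted threshold. That estimate did not converge and gave control array 3 a weight of 29.0 in the region fit, against 2.20 for the next array.

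The groups were fully separated, all 3 arrays of one above all 3 of the other, in 977 regions (4.44%, where chance gives 10%). The values were higher in the chromium-restricted group in 548 of these regions and lower in 429. A difference of at least 0.3 on the log2 scale was present in 17 of them, 6 with higher and 11 with lower values after chromium restriction of the dams. With normexp background correction in place of the processed signals, the 17 differences had sizes of 0.041 to 0.17 in the same directions, and 0 of them reached 0.3. Each of the 17 had an adjusted p of 1.0 in limma, so none is counted as changed.

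Among the regions with lower values, the smallest unadjusted p of all regions belonged to chromosome 5 from 86897516 to 86899178. Its mean log2 ratio was 0.083 ± 0.039 in the chromium-restricted group and 0.45 ± 0.16 in the control group (SD, n = 3 each). The difference was -0.37 (SE 0.094, 95% confidence interval -0.58 to -0.15; limma unadjusted p = 0.00415), and all 7 of its probes had the same direction. Only 2 of the 7 were well above background in both channels on all arrays. A region on chromosome 14 from 54877607 to 54879299 had -0.55 ± 0.097 against -0.25 ± 0.040, a difference of -0.31 (SE 0.080; limma unadjusted p = 0.00451). On the X chromosome, the region from 47140983 to 47142577 had -0.41 ± 0.11 against -0.10 ± 0.094, and all 8 of its probes were lower in the chromium-restricted group. All probes shared the direction in 6 of the 17 regions, each of them with lower values. The regions were chosen by the mean over these probes, so agreement between probes is no separate support. The largest difference of the 17 was -0.45 (SE 0.16), in a region of 3 probes on chromosome 3 from 35564790 to 35565259. Its means were 0.91 ± 0.28 and 1.36 ± 0.25, and 0 of its 3 probes were well above background in both channels on all arrays. Without chromium-restricted array 2 its difference was -0.29 and no longer the largest. Within scans 1, 2 and 3 its difference was -1.7e-04, -1.03 and -0.32. Chromosome 5 held another such region, from 88956423 to 88958154, with a difference of -0.33. Chromosome 14 held another from 102007910 to 102009667, with a difference of -0.32. The remaining regions with lower values started at 43855698 on chromosome 19 (-0.32), 132816804 on chromosome 6 (-0.39), 83494899 on chromosome 18 (-0.32), 84016261 on chromosome 3 (-0.34) and 87030607 on chromosome 2 (-0.38). Without control array 2 the difference on chromosome 18 was -0.21, and without chromium-restricted array 1 that on chromosome 2 was -0.22. The difference on chromosome 3 from 84016261 was -0.0026, -0.75 and -0.28 within scans 1, 2 and 3.

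Among the regions with higher values, chromosome 17 from 38219422 to 38220877 had a mean log2 ratio of -0.14 ± 0.027 in the chromium-restricted group and -0.53 ± 0.19 in the control group (SD, n = 3 each). The difference was 0.39 (SE 0.10; limma unadjusted p = 0.00531), and 5 of its 7 probes had this direction. Only 2 of the 7 were well above background in both channels on all arrays. The region on chromosome 10 from 79421597 to 79423241 had 0.14 ± 0.045 against -0.20 ± 0.18, a difference of 0.34 (SE 0.10; limma unadjusted p = 0.00928). On chromosome 15, the region from 3253035 to 3254681 had -0.13 ± 0.21 against -0.52 ± 0.15, a difference of 0.39. Chromosome 6 from 48036093 to 48037742 differed by 0.37, or 0.20 without control array 2. Chromosome 12 from 53107066 to 53107951 differed by 0.32, or 0.21 without chromium-restricted array 3. The region on chromosome 3 from 106487173 to 106488333 differed by 0.36 (SE 0.18, 95% confidence interval -0.050 to 0.78). Its difference was 0.13 without chromium-restricted array 1, 0.085 with flagged spots kept and -0.0023 with the median over its probes in place of the mean.

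**Figure D1:**
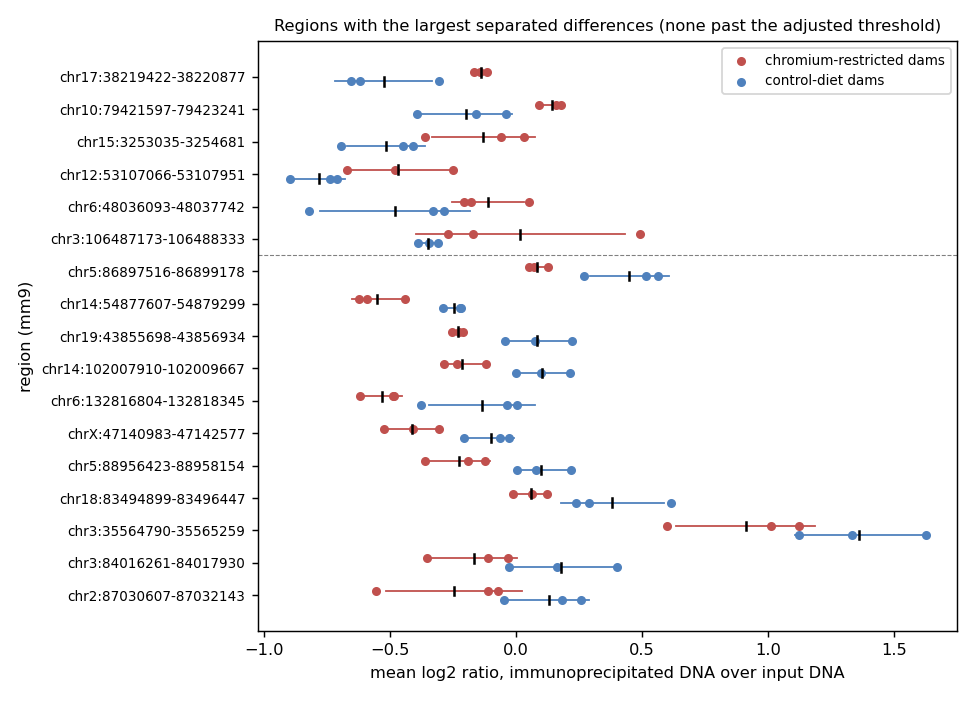
Mean log2 ratio of immunoprecipitated over input DNA in each of the 17 separated regions, with 1 point per array, a black tick at each group mean and a horizontal line of 1 SD to each side (n = 3 per group; 6 regions with higher values above the dashed line, 11 with lower values beneath it). By selection, all points of one group lie above all points of the other in each region, and each adjusted p was 1.0 in limma.

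In 9 of the 17 regions, most probes were not well above background in both channels on all arrays. When only probes well above background were kept, 8 of the 17 regions still had at least 3 probes, all with the same direction. Their sizes were then between 0.081 and 0.31, and 1 of the 8, on chromosome 6 from 48036093 to 48037742, still reached 0.3. The authors' deposited table gave the same direction for all 17, with differences between -0.18 and 0.20 on its own log scale, whose base is not stated. Both alternatives reuse the arrays by which the regions were chosen, so the shared direction is no separate support.

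The second comparison asked whether arrays of a group resembled each other more than arrays of different groups. Over regions, Pearson correlations between arrays ran from 0.909, for control arrays 1 and 2, to 0.985, for chromium-restricted array 2 and control array 1. These correlations are across regions, which are not independent replicates. The mean correlation was 0.946 within groups and 0.955 between groups, a difference of -0.0092. All 10 ways to split the 6 arrays into 3 and 3 gave a value at least as high as this one. The first principal component of the region values held 61.3% of the variance. It followed the log2 median input signal of the arrays with Pearson r = 0.96 (exact permutation p = 0.00972, n = 6) and Spearman rho = 0.943 (exact permutation p = 0.0167, n = 6). Without the 2 arrays farthest from the median input signal, r was 0.916. The input signal is also the denominator of the log2 ratios, so the component and the brightness are not separate measures. The group means of the first component differed by 1.69 on an axis where the arrays ran from -20.3 (control array 2) to 19.8 (control array 1) (exact permutation p = 0.8, n = 3 per group).

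**Figure D2:**
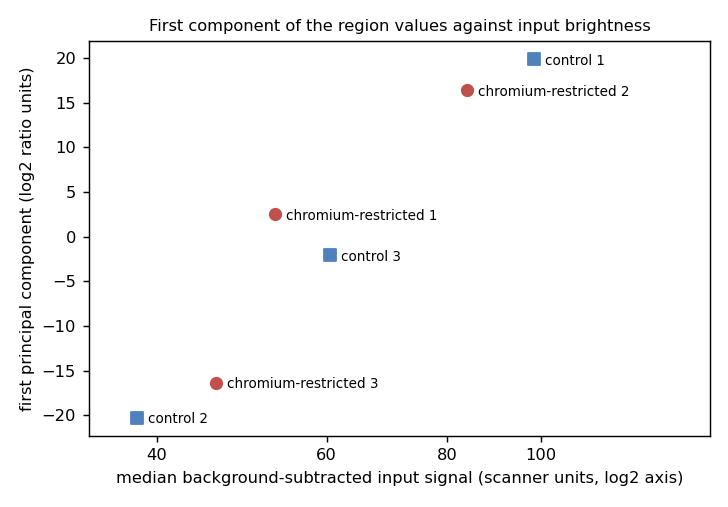
First principal component of the region values (log2 ratio units) against the median background-subtracted input signal of each array (scanner units, log2 axis), with circles for chromium-restricted and squares for control arrays. The component rises with the input signal over the 6 arrays (r = 0.96), and both groups are spread along it.

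Per-array summaries were compared with two-sided exact permutation tests, whose smallest possible p with 3 arrays against 3 is 0.1. The interquartile range of the log2 ratios was 1.63 ± 0.056 in the chromium-restricted group and 1.62 ± 0.048 in the control group (SD, n = 3 each; exact permutation p = 1). Within scans it was 1.60 against 1.67 in scan 1, 1.69 against 1.57 in scan 2 and 1.59 against 1.64 in scan 3, chromium-restricted value first. X-chromosomal regions lay 0.0024 ± 0.014 above autosomal regions in the chromium-restricted group and 0.015 ± 0.0048 above them in the control group (log2; SD, n = 3 each; exact permutation p = 0.3). The same difference was 0.017 against 0.012 in scan 1, 0.0019 against 0.014 in scan 2 and -0.011 against 0.021 in scan 3. Input signal was present on the Y chromosome on every array: between 65% and 87% of 100 probes were well above background. The groups averaged 74 ± 9.17% and 74 ± 11.5% (SD, n = 3 each; exact permutation p = 1). Mean log2 ratios per chromosome gave a lowest exact permutation p of 0.5 among 21 chromosomes (adjusted p = 1, n = 3 per group). The largest of these differences, -0.061, was that of the 15 regions on the Y chromosome. The sex of the animals was not derived from the X and Y values.

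Regions with very low log2 ratios were shared by both groups. A mean below -2 over the 6 arrays was found in 345 regions (1.57%), and 245 of them were below -2 on every array. Their mean was -2.79 ± 0.30 in the chromium-restricted group and -2.78 ± 0.33 in the control group (SD, n = 3 each; exact permutation p = 1). Of the 345, 0 had an unadjusted p under 0.05 in limma. Chromosome 7 held 121 of them among 2007 regions (6.03%), chromosome 4 held 51, the X chromosome 39 and chromosome 5 held 36, while chromosomes 11, 15, 16 and 18 held 0. On chromosome 7 between 20 and 24 Mb, 78 of 112 regions were this low. On chromosome 2 between 175 and 178 Mb the count was 26 of 34, and on chromosome 4 between 60 and 62 Mb it was 17 of 22. Further groups lay on chromosome 4 between 145 and 147 Mb, with 14 of 18 regions, and on the X chromosome between 30 and 32 Mb, with 11 of 12. In all, 201 of the 345 lay in 21 windows of 1 Mb with at least 5 such regions. The highest count in any window was 6 when 345 regions were drawn at random 1000 times. An example is chromosome 7 from 66933838 to 66935376, with -4.88 ± 0.16 in the chromium-restricted group and -4.88 ± 0.22 in the control group (SD, n = 3 each). The threshold of -2 and the windows were chosen after the values had been seen.

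**Figure D3:**
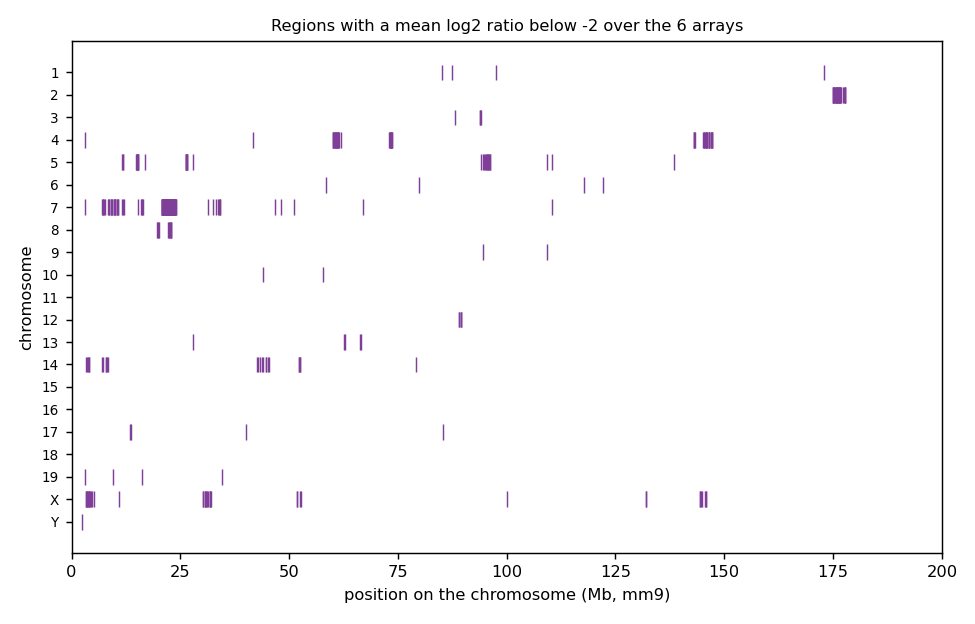
Positions (Mb, mm9) of the 345 regions with a mean log2 ratio below -2 over the 6 arrays, 1 vertical line per region, by chromosome. Dense groups lie on chromosome 7 between 20 and 24 Mb (78 of 112 regions) and on chromosome 2 between 175 and 178 Mb (26 of 34).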

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

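Among the alternatives, the fit with the median input signal as a covariate and the array weights from the gene by gene algorithm were chosen after seeing the data. The count of regions past the adjusted threshold in limma was 0 under 22 of 23 alternatives, and that of probes 0 under 18 of 19. The exception was array weights with the default algorithm, with 1654 regions and 53189 probes and lowest adjusted p of 0.0293 and 0.00597. That algorithm did not converge and gave control array 3 a weight of 29.0 for regions and 123 for probes. The gene by gene algorithm gave this array 4.32 and 5.94, and 0 calls. At an unadjusted p under 0.05, the 197 regions became 37 with normexp, 94 with only probes well above background, 436 with the unmoderated statistic, 848 with the input covariate, 1894 with gene by gene weights and 6479 with default weights. The 2259 probes became 441 with normexp, 863 with only probes well above background, 1335 with the authors' table, 6805 with the input covariate, 28480 with gene by gene weights and 77195 with default weights. Leaving out 1 array gave 119 to 558 regions and 1746 to 4248 probes. Without control array 1 the counts were 558 and 4153, and without chromium-restricted array 2 they were 332 and 4248. Regions numbered 130 without chromium-restricted array 1 and 119 without control array 3. The cause was not tested. With the replicate block, which is also the scan block, 0 regions and 0 probes passed, and 112 regions and 2294 probes had an unadjusted p under 0.05. Deviations of same-numbered arrays from their group means correlated at 0.145, -0.591 and 0.197 for numbers 1, 2 and 3. Chromium-restricted array 2 correlated best with control array 1 (0.674) and chromium-restricted array 3 with control array 2 (0.579). The first pair had the brightest inputs and the second the dimmest. These correlations went with input brightness and do not decide whether the numbers pair the arrays beyond the shared scan. The difference in interquartile range, 0.0012, ran from -0.031 to 0.022 when 1 array was left out. It was -0.031 without chromium-restricted array 2 and -0.025 without control array 2 (cause not tested). The other alternatives gave 0.0011 to 0.033. Within minus between correlations stayed between -0.016 and -0.0029, and the X difference between -0.020 and -0.0062. Of the 17 named regions, 16 kept their direction under every alternative that gave a value. The exception, on chromosome 3 from 106487173, was -0.0023 with the median over probes. With normexp, whose offset draws all log2 ratios toward 0, the 17 differences shrank to sizes of 0.041 to 0.17. Leaving out 1 array moved 6 of the 17 by over 1.5 times toward 0: the regions on chromosomes 2 (-0.22) and 3 from 106487173 (0.13) without chromium-restricted array 1, on 3 from 35564790 (-0.29) without array 2, on 12 (0.21) without array 3, and on 6 from 48036093 (0.20) and 18 (-0.21) without control array 2. The GC correction, alone or with the replicate block, and all alternatives for genes, gene lists and probe classes were not run. The 95% confidence interval of a probe extended by a median of 0.44 to each side for bright probes and 0.66 for others.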

Other observations

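The tests of input labelling, of a dye trend, of multi-copy sequence, of probe length, of neighbouring probes and of the splits for regions were chosen only after results had been seen. For those of probes near background in the input pattern, of broad shifts and of the splits for probes, the values that prompted the test had been seen, but not the result of the test itself. At the upper end of the log2 ratios, the region with the highest mean lay on chromosome 10 from 62891574 to 62892980, with 1.96 ± 0.075 in the chromium-restricted group and 1.80 ± 0.079 in the control group (SD, n = 3 each). A region on the X chromosome from 12513044 to 12514336 had 1.46 ± 0.14 and 1.46 ± 0.25. The 99th percentile of region means was 0.86 and the 1st was -2.41, so the low tail was longer than the high one. By chromosome, the mean over all arrays was lowest for the Y chromosome (-0.45, 15 regions) and chromosome 7 (-0.35, 2007 regions), and highest for chromosome 11 (-0.082).

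Small shifts shared by many neighbouring regions were tested as a hypothesis of their own. Of 1504 windows of 1 Mb with at least 5 regions, 0 passed the adjusted threshold in limma and 2 (0.133%) had an unadjusted p under 0.05. The largest difference was -0.15 (SE 0.072), and the 95% confidence interval of a window extended by a median of 0.092 to each side. Broad shifts well beyond that size are argued against, and smaller ones stay open.

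The main axis of difference between the arrays went with the brightness of their input channel, with arrays of both diets at either end. The first component of the region values followed the median input signal with r = 0.96 over 6 arrays. This is the pattern itself, and the input signal is also the denominator of the log2 ratios. Input labelling, DNA preparation, the animals and this shared term therefore cannot be told apart as its cause. The split along this component, chromium-restricted arrays 1 and 2 and control array 1 against the rest, called 1144 regions (5.20%), while the split of the 3 brightest inputs from the 3 dimmest called 0 (4560 at an unadjusted p under 0.05). The tables argue against a brightness-dependent dye trend as the whole cause of the first split, because 1280 regions were called after loess, and against probes near background, because 15.3% of regions were called when only probes well above background were kept. The diets differed by 1.69 along this axis (exact permutation p = 0.8, n = 3 each).

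The regions with log2 ratios below -2 lay close together on a few chromosomes in both groups. Relative to other regions, their immunoprecipitated signal was -1.50 on the log2 scale (SD 0.038 over arrays). Their input signal was 1.22 higher (SD 0.30). Extra copies alone would not lower the immunoprecipitated signal. However, choosing regions by a low ratio itself favours such values, so they do not decide whether multi-copy sequence is the whole cause. Extra copies could still contribute part of the low ratios. Log2 ratios were shuffled 100 times among probes of the same length. A median of 25 and at most 36 regions then lay below -2, against 345 measured. The highest count narrowly missed the bound chosen for excluding probe length, in a test written after results had been seen. Every shuffle gave far fewer such regions than were measured. By the bound chosen, however, the test does not decide whether probe length is the whole cause, and a part played by it stays open. Low methylation or a low density of CpG sites in these stretches stays open, and no biological explanation was tested, as the design names none that differs along the genome.

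Neighbouring probes under 300 bp apart had nearly unrelated log2 ratios, with a correlation of 0.0976 over 134899 pairs, although sheared fragments would be expected to span several of them. The correlation was no higher, at 0.0861, among probes well above background. Keeping only these selects on both channels of the ratio, which may itself lower the correlation. This value therefore does not decide whether probes near background play a part. Wrong probe positions as the whole cause are argued against, since input signals of the same neighbours correlated at 0.244. Single-probe log2 ratios correlated at 0.892 or more between any pair of arrays, so differences between single probes lasted from array to array. Hybridisation strength may account for the low correlation of neighbours. These values cannot tell it apart from lasting differences in methylated DNA between probes. In the authors' deposited table the same neighbours correlated at 0.671, and their group differences at 0.621 against 0.0120 for the scanner ratios, which is consistent with smoothing over a short range in that table.

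The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For regions past the adjusted threshold the real split gave 0 and the highest other 1144, and for probes the real split gave 0 and the highest other 0. With a real count of 0, all 10 splits had to reach it, so this tally decides nothing. The split with 1144 regions, the one of the 10 that called most, follows the order of the arrays on the first component, whose cause stays open.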
